A study of Mus musculus with 6 samples.

How the data were processed

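RNA from 6 samples of female BALB/c mice was amplified, labelled with Cy5 and hybridised to 1-colour arrays, per the labels' protocols. The values are those of the deposited table of processed values, which holds linear intensity for 26423 probes on each array, with no scanner output used here. Per the submitters' processing notes, the authors used limma, with no version and no role given. The array's background correction, scaling, probe filter and detection flags are not given in the sources used here. The deposited intensity medians differed between arrays (223, 185, 179, 198, 207 and 224 on those labelled mock brain, SHT brain, mock ovary, SHT ovary, mock uterus and SHT uterus), so the arrays had not been brought to 1 median. Between 20 and 30 probes per array were at or below 0. Up to 5 probes per array read 65000 or more, which was taken as the top of the intensity scale.

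Groups were taken from the labels alone, as 3 tissues by 2 treatments with 1 array in each, and stayed as labelled after the marker check went against 4 labels. Arrays are therefore named by their labels throughout. There are 720 ways to give the 6 labels to the 6 arrays, of which 8 place each array in the tissue of its profile, and 1 of these keeps every treatment label. The values do not settle which holds, and no array was moved. The labels do not say whether the tissues came from the same mice.

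Each array was raised to the 5th percentile of its positive values (5.66 to 6.66) and put on the log2 scale, with no scaling between arrays. Of the probes, 20377 carried 1 gene symbol in the platform annotation, 0 carried several and 6046 carried none. Unnamed probes entered the array correlations and the percentiles but no gene comparison. Symbols were updated through a RefSeq gene table of the mouse assembly GRCm38.p6, where 18213 matched a current symbol, 2126 a synonym and 38 were kept as given. Positions are not given, since the build behind the probe design is not given in the sources used here. Where several probes named a gene (2278 genes), the probe with the highest mean over the 6 arrays was used, which left 17742 genes. Folds are reported relative to the median gene of each pair. A fold is called a lower bound ("at least") where the brighter array was at the top of the scale, or where the dimmer array read under its 95th percentile of the olfactory receptor genes (275 to 541), which then took the place of its value. The latter rule was chosen after the data were examined. Counts do not use it, so a counted gene can read under that percentile on both arrays. List medians are given as read and again with members at their bounds.

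For each labelled tissue, the SHT array was compared with the mock array. With 1 array per group there was no test and no p-value. Genes counted had a pair mean above the median of such means over all probes (the level floor) and a difference of at least 2-fold. The 45 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. A list's median was placed among 10000 random lists of the same size matched on level in 20 bins, as a description of those arrays. On simulated differences over 17742 genes for the lists in brain, 6 of 200 random lists (3%) fell outside the central 95%. In that simulation, 20 of 20 lists shifted by 0.5 on the log2 scale were recovered. This recovery does not carry over to the real pair labelled brain, where 25 of 45 lists lay outside. Inside lay lists with medians above 0.5, such as sex hormone receptors and coregulators (0.96) and cholesterol synthesis (0.90). The simulated 3% says nothing about lists whose members vary together. Named genes were the 12 with the largest increase and the 12 with the largest decrease above the floor in each tissue, without placeholder symbols. Up to 4 members with the largest difference were named from each list described. For the average over tissues, the rule took up to 10 genes each way at an adjusted p under 0.05, or otherwise the 8 each way with the largest smallest-of-3 difference in the same direction. Markers quoted in the label check were picked after their values were seen.

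The average SHT effect was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, labelled tissue as a block, two-sided, Benjamini-Hochberg adjustment) on 10763 genes above the floor. It measures the spread between the 3 labelled tissues and not between mice. On simulated arrays with matched blocks and 10763 genes, the test of the average SHT effect recovered 79% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, with 0 false calls. That simulation used the noise between the closest arrays and no mismatched labels. Alternatives were quantile normalization, centring on the median, removal of a lowess trend (span 0.4), the mean of a gene's probes, other level floors, a 3-fold threshold, no eBayes trend, no block and each tissue left out. Raising values to the olfactory receptor median was added after the data were examined. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.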

Results

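Gene expression was measured on 6 arrays of 26423 probes, each hybridised with Cy5-labelled RNA amplified from a tissue of female BALB/c mice. The labels give brain, ovary and uterus, each from untreated mice (mock) and from mice given SHT (Sheng-Hua-Tang), a herbal decoction, by mouth at 200 mg/kg for 7 days. Each of the 6 groups held 1 array, so no difference within a tissue has a replicate check, and the number of arrays limits the precision of every value. Median intensities lay between 179 on the array labelled mock ovary and 224 on the array labelled SHT uterus. The 529 olfactory receptor genes, which most tissues do not use, had medians between 29.0 and 40.7 and 95th percentiles between 275 and 541, which gave the spread of the background.

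The marker genes of the 3 tissues went against the labels of 4 of the 6 arrays. Snap25, a protein of neurotransmitter release, read 58204 on the array labelled mock brain and 60038 on the array labelled SHT ovary, but 210 on the array labelled SHT brain. Mbp, a myelin protein, read 24553 and 23439 on the first 2 of these arrays and 77.4 on the third. The gonadal genes ran the other way. Hsd3b1, a steroid-producing enzyme, read 40566 on the array labelled SHT brain and 51780 on the array labelled mock uterus, and 65.3 on the array labelled SHT uterus. Zp2, a protein of the egg coat, read 4579 and 8992 on the same 2 arrays and at most 67.2 elsewhere. Hoxa13, a homeobox gene of the lower reproductive tract, read 214 on the array labelled mock ovary and 175 on the array labelled SHT uterus, and at most 2.32 on the others, all under the 95th percentile of the olfactory receptor genes. Krt5 and Krt14, keratins of stratified epithelium, read 36716 and 65580 on the array labelled mock ovary and 29948 and 64964 on the array labelled SHT uterus. Krt14 was thus at the top of the intensity scale on the first of these arrays and near it on the second.

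**Figure D1:**
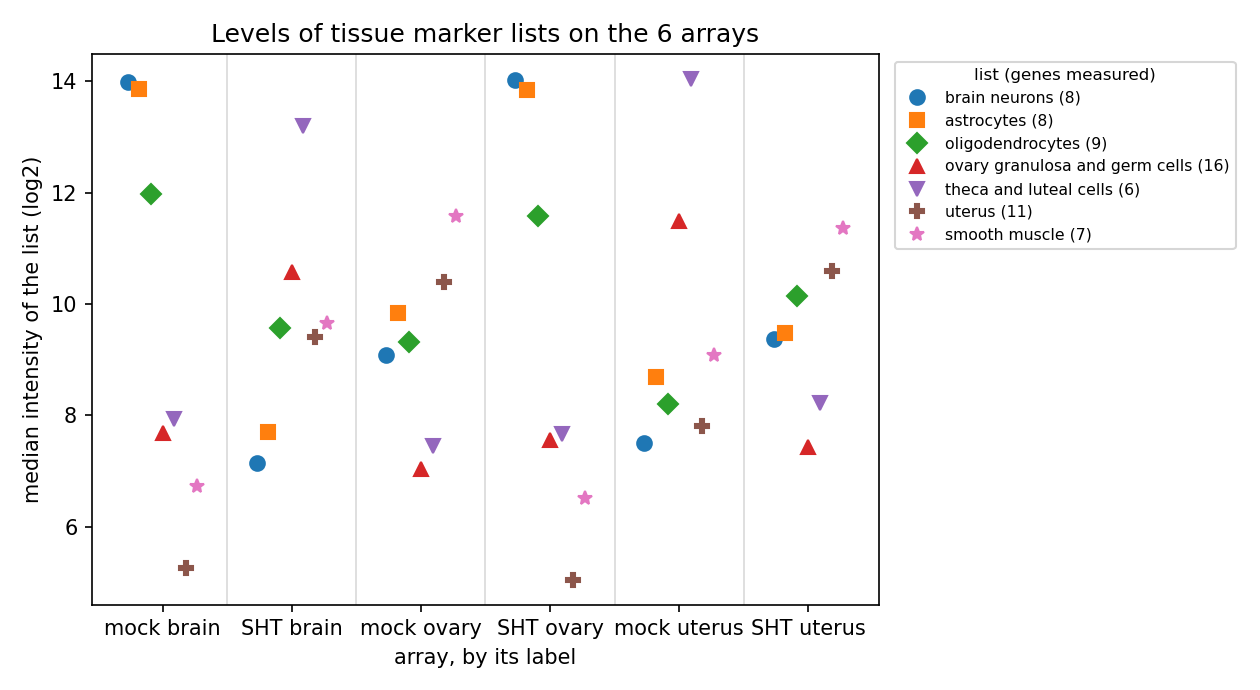
Median log2 intensity of 7 tissue marker lists (vertical axis) on each of the 6 arrays, named by label (horizontal axis), with 1 point per list and array and no error bars, since each group held 1 array. The median of the neuron list was 14.0 on the arrays labelled mock brain and SHT ovary, and 7.14 on the array labelled SHT brain.

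Scored on these lists, the arrays labelled mock brain and SHT ovary had the profile of brain, those labelled SHT brain and mock uterus that of ovary, and those labelled mock ovary and SHT uterus that of uterus. A profile is the highest of 3 scores, so it names only the nearest of these 3 tissues. That score, in log2 units, was 3.85 and 3.78 for brain, 2.75 and 3.88 for ovary, and 1.08 and 1.70 for uterus. The keratin and squamous list had median intensities of 26915 and 7649 on the arrays labelled mock ovary and SHT uterus. The uterus list had 1338 and 1539 there. No squamous tissue was scored, so a uterine profile does not establish uterus. The profile was that of the label on 2 arrays, labelled mock brain and SHT uterus. The probe named Mog, after a myelin gene, ran opposite to Mbp, with 2044 and 1605 on the arrays with a brain profile and between 3858 and 6021 on the others, and whether it measures that gene is not known here. Across probes, which are not independent replicates, the 3 closest of the 15 pairs of arrays never shared a tissue label. The arrays labelled mock brain and SHT ovary correlated at 0.996 (Pearson, log2 intensity), those labelled SHT brain and mock uterus at 0.981, and those labelled mock ovary and SHT uterus at 0.972. The 3 pairs that share a tissue label correlated at 0.813 to 0.931. Every direction below is therefore a difference between arrays named by their labels, and is not assigned to a tissue or to the treatment.

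**Figure D2:**
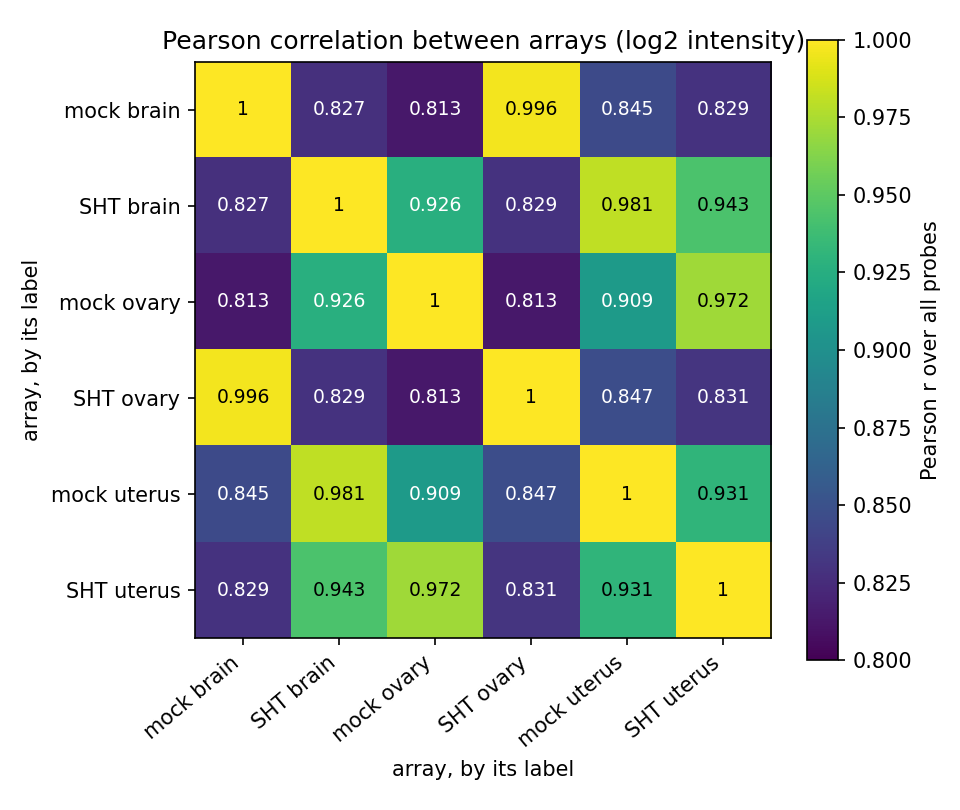
Pearson correlation of log2 intensity over all probes for each pair of the 6 arrays, named by label on both axes, with colour and number giving the coefficient. The highest values, 0.996, 0.981 and 0.972, join arrays with different tissue labels, while the arrays labelled mock brain and SHT brain stand at 0.827.

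The first comparison asked which genes differed in brain after SHT. Neuronal and glial genes were lower, and gonadal, oestrogen-responsive uterine and cell cycle genes higher, on the array labelled SHT brain than on the array labelled mock brain, 2 arrays with the profiles of ovary and brain. Of 10746 genes above the level floor, 2361 were at least 2-fold higher and 2575 at least 2-fold lower, together 45.9%. With each array centred on its median the counts were 2997 higher and 2046 lower, a share of 59.4% higher against 47.8% as deposited. The median gene differed by -0.12 on the log2 scale, and folds and list medians are given relative to it. All 72 genes named for their size of change in the 3 comparisons read inside the background spread on the dimmer array. Their folds are therefore lower bounds, against that array's 95th percentile of the olfactory receptor genes, and set no order among them. Ddn, a dendritic protein, was at least 146-fold lower, the axonal motor Kif5a at least 128-fold, Cplx1 at least 98.0-fold, and Eef1a2, a translation elongation factor of neurons and muscle, at least 93.2-fold. The neuropeptide gene Cck was at least 85.3-fold lower, Zfp365 at least 79.8-fold and Nefm, a neurofilament protein, at least 73.5-fold. The lower bounds of Camkv, Svop, Cpne6, Sncb and Tns2, also lower, ran from 35.4-fold to 55.6-fold. Hsd3b1 was at least 81.3-fold higher, Sprr2f at least 79.3-fold, Arg1 at least 64.0-fold and Lcn2 at least 58.4-fold. The lower bounds of Plet1, the epithelial adhesion gene Epcam, Krt8, a keratin of simple epithelia, Spink12, Fcgbp, Apoa4, Tmem45b and Dpt, also higher, ran from 10.7-fold to 37.2-fold. With the mean of a gene's probes in place of its brightest probe, the bounds fell to 19.3-fold for Kif5a, 5.38-fold for Tns2 and 16.5-fold for Epcam.

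Among the fixed gene lists, 25 of 45 had a median outside the central 95% of random lists matched on level in the pair labelled brain, 18 above and 7 below. Chance gives 2.25 where the members of a list vary independently. Members that vary together bring more lists outside, and 9 of 45 lay outside even between the 2 arrays with a brain profile. The neuron list had a median log2 difference of -7.31, below all 10000 random lists. All 7 of its members above the floor were at least 2-fold lower, among them Snap25 (at least 195-fold), Gap43 (at least 60.7-fold) and Camk2a (at least 45.4-fold). All 11 genes of glutamate and GABA signalling above the floor were lower, with a list median of -4.90. They included the receptor genes Grin1 (at least 34.3-fold) and Gabrb2 (at least 30.8-fold), the vesicular transporter Slc32a1 (at least 34.8-fold) and the GABA-producing enzyme Gad2 (at least 18.6-fold). Astrocyte genes had a median of -3.69, with Slc1a2, a glutamate transporter, at least 127-fold lower. Oligodendrocyte genes had a median of -3.56, with 7 of 8 lower and 1 higher. The list of dopamine, serotonin and opioid signalling had a median of -1.83, with 8 of 11 genes lower, while Slc18a2, a vesicular monoamine transporter, was at least 4.81-fold higher. The theca and luteal list had a median of 6.24, with Star, which carries cholesterol into mitochondria for steroid synthesis, at least 18.4-fold higher. The granulosa and germ cell list had a median of 3.74, with 9 of 12 genes higher, among them Inha (33.0-fold), Foxl2 (at least 24.7-fold) and Zp2 (at least 9.18-fold). Oestrogen-responsive uterine genes had a median of 6.17, with 10 of 12 higher, including Clca1 (at least 132-fold), C3 (at least 69.9-fold) and Lcn2 (at least 58.4-fold). Of 14 cell cycle genes above the floor, 13 were higher, with a list median of 3.70, and Top2a was at least 5.63-fold higher. All 7 genes of antigen presentation above the floor were higher, with a list median of 3.62, among them H2-Aa (at least 20.7-fold) and Cd74 (at least 2.91-fold). The adipocyte list had a median of 4.11, and Cfd was at least 43.9-fold higher. The extracellular matrix list had a median of 3.36, with 13 of 15 higher. The probe named Col1a1 ran against the list, at least 19.2-fold lower, and whether it measures that gene is not known here. The keratin and squamous list had a median of -0.11, inside the range of random lists, with 1 of 7 genes above the floor higher and 2 lower. With members inside the background spread set to their bounds, and to 0 where both arrays read inside it, the medians were -5.56 for neurons, -3.85 for glutamate and GABA signalling, -3.19 for astrocytes, -2.08 for oligodendrocytes and -1.11 for dopamine, serotonin and opioid signalling. They were 4.18 for theca and luteal cells, 3.30 for oestrogen-responsive uterine genes, 2.42 for extracellular matrix, 2.37 for antigen presentation, 2.26 for adipocytes, 1.62 for granulosa and germ cells and 1.35 for cell cycle. With the mean of a gene's probes the bounds fell to 18.4-fold for Camk2a, 7.56-fold for Slc1a2, 6.94-fold for Star, 6.47-fold for Gabrb2, 6.29-fold for Grin1, 2.88-fold for Foxl2 and 1.27-fold for Cd74.

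The same question was put to ovary. Here the directions were nearly the opposite: neuronal genes were higher, and keratin, matrix and muscle genes lower, on the array labelled SHT ovary than on the array labelled mock ovary, 2 arrays with the profiles of brain and uterus. Of 10693 genes above the floor, 2721 were at least 2-fold higher and 2269 lower, together 46.7%. The direction of the majority turned with the scaling: the counts were 2445 higher and 2526 lower with each array centred on its median, and 2376 and 2548 after quantile normalization. The median gene differed by 0.13. Ddn was at least 130-fold higher, Cck at least 82.4-fold, the calcium pump Atp2b2 at least 51.0-fold, Camkv at least 48.7-fold, Trim9 at least 40.7-fold and Ntm at least 39.4-fold. The lower bounds of the heparan sulphate enzyme Hs3st2, Grin1, Gabrb2, Neurod2, a transcription factor of neurons, Sez6 and Baalc, also higher, ran from 14.5-fold to 30.2-fold. Lgals7 was at least 168-fold lower, Sprr2d at least 110-fold, Arg1 at least 106-fold and Calml3 at least 92.5-fold. Lce3f, a gene of the cornified envelope, was at least 64.7-fold lower, S100a14 at least 63.6-fold and Krtdap, a gene of keratinocyte differentiation, at least 58.9-fold. The lower bounds of the epidermal protease inhibitor Spink5, Dpt, Spink12, Il1f6 and Slurp1, also lower, ran from 22.0-fold to 36.9-fold. With the mean of a gene's probes the bounds fell to 5.17-fold for Grin1, 5.07-fold for Gabrb2, 2.25-fold for Trim9 and 26.6-fold for Calml3.

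In the pair labelled ovary, 26 of the 45 lists lay outside the central 95%, 8 above and 18 below. All 8 neuron genes above the floor were at least 2-fold higher, with a list median of 5.12, including Camk2a (at least 36.6-fold) and Rbfox3 (at least 35.1-fold). All 11 genes of glutamate and GABA signalling above the floor were higher, with a list median of 4.30. The astrocyte and oligodendrocyte lists each had a median of 3.37, and Cldn11, a tight junction gene of myelin, was at least 60.5-fold higher. All 13 genes of the keratin and squamous list above the floor were lower, with a list median of -6.66, including Krt1 (at least 70.4-fold), Krt15 (at least 44.5-fold) and Sprr3 (at least 44.1-fold). The adipocyte list had a median of -5.62, with the fatty acid binding protein gene Fabp4 at least 38.6-fold lower. Of 17 matrix genes above the floor, 16 were lower, with a list median of -4.78, among them Col1a2 (at least 52.1-fold) and the collagen cross-linking enzyme Lox (at least 18.4-fold). The 3 smooth muscle genes above the floor were lower, Acta2 39.4-fold, Des at least 36.9-fold and Smtn 22.6-fold, with a list median of -4.54. All 11 oestrogen-responsive uterine genes above the floor were lower, with a list median of -4.46. The cell cycle list had a median of -3.16, with 11 of 14 lower. The lists of granulosa and germ cells and of theca and luteal cells had medians of -0.01 and -0.34, inside the range of random lists. With members at their bounds the medians were 4.90 for neurons, 3.23 for glutamate and GABA signalling, 2.28 for astrocytes and 1.95 for oligodendrocytes. They were -5.47 for the keratin and squamous list, -3.99 for extracellular matrix, -3.24 for oestrogen-responsive uterine genes, -3.05 for smooth muscle, -2.10 for adipocytes and -0.87 for cell cycle. With the mean of a gene's probes the bounds were 13.2-fold for Camk2a, 6.37-fold for Lox and 53.8-fold for Acta2.

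In the third comparison, of uterus after SHT, keratin, muscle and neutrophil genes were higher and steroid-producing, oocyte and ciliated cell genes lower on the array labelled SHT uterus than on the array labelled mock uterus, 2 arrays with the profiles of uterus and ovary. Of 10765 genes above the floor, 1388 were at least 2-fold higher and 914 lower, together 21.4%. The median gene differed by -0.02. Sprr2d was at least 220-fold higher, Krt6b at least 150-fold, Krt16 at least 134-fold, Psca at least 108-fold, Ppbp, a platelet chemokine, at least 105-fold, Krt5 at least 103-fold and Krt15 at least 98.4-fold. The lower bounds of Prss22, Krtdap, Actn4, Ucp1, the uncoupling protein of brown fat, and Duoxa1, also higher, ran from 13.1-fold to 43.9-fold. Hsd3b1 was at least 161-fold lower, the oviduct glycoprotein gene Ovgp1 at least 98.9-fold, Inha at least 91.8-fold, Akr1cl at least 79.7-fold and Hao2 at least 63.7-fold. The lower bounds of the oocyte genes Padi6, Nlrp14 and Zp2, of Apoa4, Serpina5, Mmel1 and of Amhr2, which encodes the receptor of anti-Müllerian hormone, all lower, ran from 10.1-fold to 43.3-fold.

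Of the 45 lists, 24 lay outside the central 95% in the pair labelled uterus, 15 above and 9 below. The keratin and squamous list had a median of 6.71, with 11 of 13 genes higher. The skeletal muscle list had a median of 3.54, with Acta1 at least 8.71-fold and Tnnc2 at least 6.59-fold higher. All 7 neutrophil genes above the floor were higher, with a list median of 2.62, among them Retnlg (77.6-fold), S100a9 (37.9-fold) and Csf3r (at least 11.95-fold), the receptor of granulocyte colony-stimulating factor. The chemokine and cytokine list had a median of 1.44, with Ccl11 40.2-fold and Il1b 26.4-fold higher. Oestrogen-responsive uterine genes had a median of 2.34, with 10 of 13 higher and 1 lower. Smooth muscle genes had a median of 1.95, matrix genes 1.41 and interferon-stimulated genes 1.19. All 6 theca and luteal genes were lower, with a list median of -5.59, including Akr1c18 (143-fold) and Star (at least 32.4-fold, and at least 14.2-fold with the mean of its probes). Of 12 granulosa and germ cell genes above the floor, 10 were lower, with a list median of -3.20, including Inha (at least 91.8-fold) and Gdf9 (at least 32.2-fold). The oviduct and ciliated list had a median of -3.59, with 7 of 9 lower, and Tekt4, a protein of ciliary microtubules, was at least 4.39-fold lower. The cell cycle list had a median of -1.36, with 10 of 16 lower. With members at their bounds the medians were 4.71 for the keratin and squamous list, 2.34 for oestrogen-responsive uterine genes, 1.74 for skeletal muscle, 1.4828 for neutrophils, 1.41 for matrix, 1.09 for smooth muscle, 0.83 for chemokines and cytokines and 0.52 for interferon-stimulated genes. They were -4.57 for theca and luteal cells, -2.01 for granulosa and germ cells, -1.90 for the oviduct and ciliated list and -1.18 for cell cycle.

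The average difference between arrays labelled SHT and mock over the 3 labelled tissues was the treatment comparison that could be tested. With the labelled tissue as a block, limma found 0 of 10763 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.99996 (Benjamini-Hochberg, two-sided, 2 residual degrees of freedom). At an unadjusted p under 0.05 there were 4 genes, far fewer than that threshold gives by chance among as many genes. The blocks join arrays with profiles of different tissues, so that the tissue difference entered the spread. By profile the 3 differences were ovary minus brain, brain minus uterus and uterus minus ovary, which sum to about 0, so that the same direction in all 3 is nearly ruled out by construction. Of genes above the floor, 2 were at least 2-fold higher in all 3 comparisons. They were Car2, a carbonic anhydrase, with log2 differences of 1.20, 2.15 and 1.80 in the pairs labelled brain, ovary and uterus, and Ovol2, an epithelial transcription factor, with 1.56, 1.78 and 1.33. With values inside the background spread at their bounds, 1 gene was left, Car2, since the difference of Ovol2 in the pair labelled uterus fell to 0.17. No gene was at least 2-fold lower in all 3. Prom1, Dusp6, Clic6, Arg2, Epsti1 and Gcnt2 followed among the genes higher in all 3 as read, and Coch, Irs3, Igfbp2, Nt5c3, Ablim1, Thop1, Stab2 and Pla2g4f came first among the genes lower in all 3. With values at their bounds, Clic6, Arg2, Coch, Irs3, Stab2 and Pla2g4f had no difference left in at least 1 pair. The smallest of the 3 differences was 0.95 for Prom1 and 0.71 for Gcnt2, and -0.50 for Igfbp2 and -0.38 for Thop1.

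The differences of the labelled tissues were correlated negatively or close to 0. Across genes, which are not independent replicates, the differences in the pairs labelled brain and ovary correlated at -0.87 (Pearson; Spearman -0.83, 10250 genes). Both pairs include an array with a brain profile, labelled mock in the first and SHT in the second, so that it enters with opposite sign and a negative correlation arises without any treatment effect. The other pairs likewise share a profile with opposite sign. Those labelled ovary and uterus correlated at -0.46 (Spearman -0.32) and those labelled brain and uterus at -0.08 (Spearman -0.05).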

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

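The tests in this part were chosen after the results were seen. For 14 gene lists fixed beforehand, the median was at least 2 log2 units above the median gene in one labelled tissue and at least 2 below it in another. With 1 array per group these differences were not tested. Between the pairs labelled brain and ovary, the medians differed by 10.63 for oestrogen-responsive uterine genes, 9.73 for adipocytes, 8.15 for extracellular matrix, 7.41 for smooth muscle, 6.86 for cell cycle and 6.10 for antigen presentation, each higher in the pair labelled brain. Between the same pairs they differed by 12.43 for neurons, 9.20 for glutamate and GABA signalling, 7.06 for astrocytes and 6.93 for oligodendrocytes, each higher in the pair labelled ovary. The pairs labelled brain and uterus differed by 11.83 for theca and luteal cells, 8.04 for steroid hormone synthesis and 6.93 for granulosa and germ cells, each higher in the pair labelled brain. Keratins and squamous epithelium differed by 13.37 between the pairs labelled uterus and ovary. With members inside the background spread at their bounds, the medians of all 14 lists still lay on opposite sides of 0, and those of 10 lists still at least 2 log2 units from it.

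These differences go with the tissue profiles, which went against the labels of 4 arrays. Scaling between arrays does not account for that, since after quantile normalization still only 2 arrays had the profile of their label. A mixture in which the labelled tissue was a large part, enough to hold its markers within 3 log2 units, is argued against for 3 arrays. The markers used were those above the median gene on the arrays with that profile. More than 3 log2 units below those arrays lay 72% of 25 brain markers on the array labelled SHT brain, and at least 57.9% of 19 ovary markers on either array labelled ovary. For uterine RNA on the array labelled mock uterus the share was 27.3% of 11 markers, which by itself leaves a mixture open there. A large part of the tissue on the arrays with a uterine profile is argued against by its squamous genes. Of the 15 measured members of the keratin and squamous list, 13 were at least 8-fold lower on the array labelled mock uterus than on both of those arrays. A mixture with uterine tissue free of squamous epithelium stays open. Mislabelled samples, with labels exchanged among the arrays, are a candidate explanation: each of the 3 profiles was found on exactly 2 arrays, and the 4 arrays out of place could be permuted among themselves to restore the tissues. Whether the exchange, if there was one, also touched the treatment labels cannot be read from these values.

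For limma's test of the average SHT effect, the real split of the arrays gave 0 genes, with 4 at an unadjusted p under 0.05, and the highest of the other splits also gave 0. Since no split can give fewer than 0, that 10 of 10 splits gave as many was fixed by the real count and says nothing about chance. Parting 6 arrays 3 against 3 also makes too few splits for a share under 0.05. The split that set the arrays labelled mock brain, SHT ovary and mock uterus against the rest gave 2074 genes at an unadjusted p under 0.05 in limma's test. It is quoted as the highest such count of the 10 splits, and its smallest adjusted p was 0.24. This split sets both arrays with a brain profile against both with a uterine profile, so it parts the arrays by tissue profile.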

How the results depend on the processing

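The use of the closest arrays as blocks, values raised to each array's olfactory receptor median and the marker check under other scalings were added after the data were examined; the other settings were fixed before. With 1 array per group, no value has a replicate spread to set a shift against. The genes at least 2-fold different numbered 4936, 4990 and 2302 in the pairs labelled brain, ovary and uterus. They stayed within 1.5 times of that under quantile normalization, median centring, lowess, the mean of a gene's probes and the raised values. Without a level floor they numbered 7441 in brain and 3714 in uterus (7462 in ovary), with the floor at the 75th percentile 2385, 2505 and 903, and at 3-fold 3091, 3310 and 1281. More or fewer genes enter by construction. All 75 list medians past the random lists and all 72 named genes kept their direction under each of these 5 settings (375 and 360 values). This was partly fixed in advance. Median centring cannot change a list median taken relative to the median gene, and the named genes were picked for their large differences. With raised values no such list median moved by more than 0.54 on the log2 scale, against 1.04 with the mean of a gene's probes. The mean of a gene's probes moved 7 of the 72 named genes by more than 1.5 times and the 3 scalings moved 0, while raised values moved 25 of them, all given as lower bounds. With list members at their bounds against the 95th percentile of the olfactory receptor genes, also added after the data were examined, 61 of the 75 list medians kept their direction, 14 were 0 and 0 turned. The lists outside the central range numbered 25 to 26 in brain, 26 to 29 in ovary and 24 to 25 in uterus. Correlations between labelled tissues ranged from -0.90 to -0.78 for brain and ovary, -0.49 to -0.36 for ovary and uterus and -0.09 to -0.04 for brain and uterus. limma's count for the average effect was 0 in every setting, with 3 to 461 genes at an unadjusted p under 0.05, with 461 without the pair labelled ovary and 126 without the pair labelled brain, against 4. With the closest arrays as blocks it was 0, with 211 at an unadjusted p under 0.05. Each of these unadjusted counts is below what the threshold gives by chance, so none is a sign of an effect. They do not speak against an effect either, since with the labelled tissue as a block the tissue difference entered the spread. Genes near the background scale are limited by signal, and those under it or at the top of the scale have bounds only.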

Other observations

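All tests and the 3 comparisons in this part were chosen after the data were examined, by which arrays were closest to each other. They are differences between single arrays named by label, with no replicate and no test, centred on each array's median. The arrays labelled SHT ovary and mock brain, both with a brain profile, differed little: 5 genes were at least 2-fold higher and 4 lower on the first, against 4 and 16 as deposited. The 5 and 4 include genes inside the background spread on both arrays, Syndig1 and Ido1 among those higher and A26c3 and Olfr998 among those lower. Tmed9 was 3.60-fold higher, Setd3 3.07-fold and S100a9, a calcium-binding protein of neutrophils, at least 1.55-fold, while Dusp18 was 3.02-fold lower and Pip5kl1 at least 1.94-fold. Of the 45 lists, 9 lay outside the central 95% of random lists, 4 above and 5 below, with 1 of their members above the floor 2-fold different as read (S100a9). The medians were 0.30 for neutrophils and for microglia and macrophages, 0.25 for oxidative phosphorylation, 0.18 for cytosolic ribosomal proteins, -0.07 for glutamate and GABA signalling, -0.08 for growth factor and Wnt signalling, -0.12 for extracellular matrix, -0.21 for immediate early genes and -0.64 for adipocytes. With members at their bounds those of neutrophils, matrix, immediate early genes and adipocytes were 0, while those of microglia and macrophages and of oxidative phosphorylation stayed at 0.30 and 0.25. Those of cytosolic ribosomal proteins, of glutamate and GABA signalling and of growth factor and Wnt signalling shrank to 0.04, -0.04 and -0.04. The arrays labelled SHT brain and mock uterus, both with an ovary profile, differed in more genes, with 510 at least 2-fold higher and 173 lower on the first (426 and 400 as deposited). Here 17 lists lay outside the central 95%, 10 above and 7 below. Oestrogen-responsive uterine genes had a median of 2.76, also with members at their bounds, with 9 of 13 higher, among them Clca1 (at least 85.1-fold), Sprr2f (64.0-fold), Lcn2 (46.6-fold) and Muc1 (at least 17.4-fold). Apobec2 was at least 11.9-fold higher. Hoxa11 and Hoxa10, homeobox genes of the uterus, were at least 2.73-fold and 4.26-fold higher, and among immediate early genes Klf4 was 13.5-fold and Fos 7.99-fold higher. Other lists above all random lists were neutrophils (1.14, 0 at their bounds), uterus (0.89, 0.005), interferon-stimulated genes (0.83, 0.20), ovulation genes (0.57, 0), immediate early genes (0.48, 0.24) and extracellular matrix (0.41, 0.41). The oviduct and ciliated list had a median of -0.59 and the granulosa and germ cell list -0.51. Hsd17b7, an enzyme of steroid and cholesterol synthesis, was 5.38-fold lower, and Cplx1 at least 3.30-fold lower.

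The arrays labelled SHT uterus and mock ovary, both with a uterine profile, had 679 genes at least 2-fold higher and 532 lower on the first (1608 and 330 as deposited, 531 and 596 after quantile normalization). The direction of the majority thus turned with the scaling. Of the 45 lists, 15 lay outside the central 95%, 9 above and 6 below. The keratin and squamous list had a median of -0.51, with 5 of 15 genes lower and 1 higher. A set of cornified envelope genes, put together after the data were examined and holding some of the genes most changed in this pair, had a median of -5.95 (-5.34 with members at their bounds), with 15 of 17 at least 2-fold lower. Kprp was 141-fold lower, Lor, the main protein of the envelope, 135-fold, the desquamation protease Klk7 at least 43.4-fold and Hrnr at least 33.2-fold. Neutrophil genes were higher, in 5 of 7 above the floor, with S100a9 29.3-fold and Csf3r at least 8.86-fold higher. The chemokine and cytokine list had a median of 0.08, inside the range of random lists, with 6 of 13 higher and 3 lower, among them Cxcl2 (at least 21.2-fold higher) and Il1b (20.9-fold higher). Interferon-stimulated genes had a median of 1.25, with 8 of 13 higher, and skeletal muscle genes 1.49 (0.74 and 0.68 with members at their bounds). Cholesterol synthesis genes had a median of -0.65. Hdc, the histamine-producing enzyme, was at least 14.7-fold higher. The probe named Syndig1 read between 0.505 and 0.776 times the level of S100a9 on each of the 6 arrays. Both read inside the background spread on the array labelled mock brain, and Syndig1 also on those labelled SHT brain and SHT ovary, where the ratio says little.

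For the oestrogen-responsive genes of the arrays labelled SHT brain and mock uterus, scaling is argued against by a list median of 2.72 after quantile normalization, and more oviduct on the first array by a median of -0.59 for the oviduct and ciliated list. A fixed share of the tissue on the arrays with a uterine profile cannot bring a gene above both of those arrays, and 3 of the 9 members, Aqp5, Clca1 and Muc1, lay at least 2-fold above both. The other 6 members would each need a share of at least 12.2%. Of the 15 measured members of the keratin and squamous list, 13 were used. These read at least 8-fold above the array labelled mock uterus on both arrays with a uterine profile. That choice set their level on the array labelled mock uterus, but not on the array labelled SHT brain. There the 13 genes allow a share of at most 7.79%, which argues against such a share too. Of the 510 genes higher on the first array, 344 were also at least 2-fold higher on an array with a uterine profile, which decides nothing because both differences are taken from the array labelled mock uterus, and 139 lay at least 2-fold above both arrays with that profile. Uterine horn epithelium without squamous tissue, hormonal stage and the treatment may each raise these 9 genes and cannot be told apart, as dissection, stage and treatment of each array are not known.

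For the cornified envelope and neutrophil genes of the arrays labelled SHT uterus and mock ovary, the cornified envelope median was -5.85 after quantile normalization. Scaling thus does not remove the difference of these cornified genes. As the set holds some of the genes most changed in this pair, the size of its median is partly a matter of selection. A smaller share of squamous epithelium as the only cause of the cornified difference is argued against by the 11 basal genes measured. Their median was -0.56, with 0 of them 2-fold different. Most of them were lower, so a modestly smaller share stays open. The basal set was also put together after the data were examined. Some of its genes do not mark squamous tissue alone: on the array labelled SHT brain Perp read 4424 and Lamb3 3410, while Krt5 read 104 and Dsg3 4.63. Among the basal genes, Krt14 was at the top of the scale on the array labelled mock ovary and near it on the array labelled SHT uterus, so its difference is only a bound. The stage of the oestrous cycle, in which cornified cells and neutrophils of the lower tract alternate, and the treatment may each account for the pattern. A difference in the tissue dissected was not tested either, and skeletal muscle genes also differed in this pair, with a median of 1.49 (0.68 with members at their bounds). With a neutrophil list median of 1.0, and stage, treatment and dissection of each array not known, these cannot be told apart.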
